A study of Mus musculus with 73 samples.

How the data were processed

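The series held 73 mouse liver samples, of which 6 whole-genome bisulfite sequencing (WGBS) libraries, 27 reduced representation bisulfite sequencing (RRBS) libraries and 7 chromatin immunoprecipitation (ChIP) libraries of the transcription factor HNF6 were compared, with the 7 HNF6 input libraries entering only through the deposited peak lists. The HNF4A and H3K27ac ChIP libraries and their inputs were not analysed here. Groups were taken from the sample titles. Per the labels, WGBS was made from hepatocytes of 8-week-old mice carrying Foxa1 and Foxa2 alleles that Cre removes, either without Cre, with the Alfp Cre transgene that acts during liver development, or 1 month after injection of a virus carrying Cre.

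The methylation tables were deposited as fractions between 0 and 1, which were multiplied by 100 to give percent. The deposited WGBS tables give 1 fraction per 400 bp FoxA site, and the deposited RRBS table gives 1 fraction per 100 bp tile, so that the unit of each RRBS count is a tile and not a single CpG. Reads were processed with Trim Galore 0.3.3 and BSMAP 2.74 on the mm9 build, per the submitters' processing notes; how sites and tiles were summarised is not given in the sources used here. None of the methylation tables gives coverage, so the depth behind each level is unknown, no interval of a level was computed, and the planned coverage minimums could not be applied. The deposited RRBS table also holds the authors' averages of 8 groups, which are also given at tiles where no library of the group had a value and were not used in tests.

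The developmental table held 33302 sites and the adult one held 28659, with 28654 in common; the latter had no sites on chromosomes 1 and 2. The levels of control 1 were identical in both tables within 0.0001 percent. In the adult table, the column headed as the first developmental null held the levels of control 2 at all 28654 common sites, and matched that developmental null at 0.96% of them; this 1 column was used for that check only. The deposited list of hyper-methylated sites, which covers 2326 separate regions, was checked to be exactly the sites whose mean developmental null level exceeded the mean control level by more than 20 points in the same 4 libraries. Counts within the list are therefore not independent evidence of direction in WGBS. Many sites overlap, and the 33302 sites covered 25640 separate regions.

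HNF6 peaks were called per library against its input, per the file headers. Control and developmental null lists came from MACS 2.1.1 and adult null lists from MACS 1.4.3, per the file headers. MACS 2.1.1 lists give fold enrichment with −log10 of the p-value and q-value, as the authors deposited them. MACS 1.4.3 lists give a score computed from the log10 of the p-value, a fold enrichment and a false discovery rate in percent, as the authors deposited them. Scores and folds were used only to rank peaks within a list. ChIP tags after the caller's filtering numbered 16760874 to 30469386 per library and input tags 17267321 to 46204748, per the file headers. The adult lists had 0% redundant tags against 38% to 62% in the other lists, and their median peak widths were 307 and 320 bp against 82 to 150 bp.

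The gene tables supplied for reference were of the GRCm38 assembly and not of mm9, so sites are named by position, and the lists of hepatocyte, transcription factor, bile acid, drug metabolism, fetal liver, bile duct, macrophage and blood, endothelial and stellate cell genes fixed beforehand could not be tested. RRBS positions were checked against WGBS sites: across 7933 tiles inside sites, control levels correlated with r = 0.759, against 0.185 with sites moved by 2000 bp and 0.018 with sites moved by 10000 bp; tiles are not independent replicates.

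Sites and tiles were tested with the moderated test of limma 3.58.1 in R 4.3.3 on the percent scale, with a variance trend and Benjamini-Hochberg adjustment at 0.05. The spread came from all RRBS groups with tiles measured in every library of the comparison, and from the libraries of a table for WGBS. Mean levels per library over a class of sites were compared with two-sided exact permutation tests in Python 3.11.15 with scipy 1.17.1, and shares of peak regions with two-sided Fisher's exact tests and Wilson 95% intervals, which cover counting error only. List tiles lay inside listed sites, and distant tiles lay more than 2000 bp from any FoxA site. Peaks were shared when they overlapped by 1 bp, and a reproducible control region was one with a peak in all 3 control lists. The fits were tested on simulated data in which 200 sites or tiles of intermediate control level were changed by known amounts. Simulated libraries had normal noise, the same spread in every group at a given site or tile, and no missing values. Real groups can differ in spread, so the shares recovered hold for these settings and are not the power of the real fits.

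These choices were made before the data were examined: groups, tests, the spread used, the rule for named sites and the other settings tried (logit scale, only the 2 groups compared, a minimum difference of 20 points, levels from 5 to 95%, replicate block, better-scored peaks, stricter overlap, sites extended by 500 bp, and each library left out). Named sites were the 10 largest rises and 5 largest falls past the threshold with every library of one group above every library of the other, the 10 best-scored HNF6 peaks of all controls and no null, and the 5 best-scored peaks of all nulls of a kind and no control. A fit of both WGBS tables joined, the best 1000 peaks per list, and list levels relative to other sites were added after seeing the data. The labels name separate samples of each group but not always separate animals, so that p-values measure the spread between samples. For limma on RRBS and on the joined WGBS tables this was the spread within all groups, not only within the 2 groups compared.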

Results

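Foxa1 and Foxa2 encode forkhead transcription factors that open chromatin in the liver. The series compared livers that lost both genes in development, through the Alfp Cre transgene, with livers that lost them in adulthood, through a viral Cre. DNA methylation at FoxA binding sites was measured by WGBS in 2 control, 2 developmental null and 2 adult null libraries. RRBS covered 4 developmental nulls and 4 controls at 20 days, 8 weeks, 4 months and 6 months of age. It also covered adult triple nulls lacking Foxa3 as well, adult double nulls after partial hepatectomy, and livers that kept 1 or more Foxa alleles. Per the labels, the controls of the triple nulls also lacked Foxa3 and received GFP in place of Cre. The controls of the hepatectomy nulls received a GFP virus and also had partial hepatectomy. HNF6, a liver homeodomain factor, was mapped by ChIP in 3 control, 2 developmental null and 2 adult null libraries. Depth per methylation level is unknown; RRBS libraries had values at 445198 to 622668 of 817277 tiles.

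In livers without Foxa1 and Foxa2 from development, mean methylation at FoxA sites lay above that of controls, mostly through the sites of the authors' hyper-methylated list. Over 33302 sites the mean level was 25.6% ± 0.052 (SD, n = 2) in developmental nulls and 21.5% ± 1.27 (n = 2) in controls. At the listed sites it was 59.9% ± 0.354 against 28.2% ± 2.29, and at the 30597 other sites 22.6% ± 0.087 against 20.9% ± 1.18. Each exact permutation test gave p = 0.333, the smallest that 2 against 2 libraries allow. By limma, 1390 sites rose and 82 fell; they covered 1200 and 76 separate regions. Of the rising sites 1373 were in the list, and 2650 list sites rose when p was adjusted over the list alone, a list chosen on these same libraries and therefore no independent evidence of direction.

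The steepest rises reached nearly full methylation from a low control level. At chromosome 16, 52267337 to 52267736, the level was 96.4% ± 1.11 in developmental nulls and 8.04% ± 6.66 in controls (SE 4.87, limma adjusted p = 0.0133), and 17.1% ± 9.21 in adult nulls. At chromosome 12, 92170469 to 92170868, it was 98.5% ± 2.08 against 12.7% ± 12.6, and at chromosome 9, 46010467 to 46010866, 86.9% ± 1.36 against 9.16% ± 0.1. The other named rises lay on chromosomes 3, 6, 7, 11 and 13, with differences of 76.1 to 81.3 points, and the chromosome 7 pair overlapped. Sites that fell included chromosome 9, 25135611 to 25136010, at 0% in both developmental nulls and 91.7% ± 2.36 in controls, with 21.8% ± 30.8 in adult nulls, and chromosome 14, 62422815 to 62423214, at 5.33% ± 0.1 against 72.7% ± 3.78.

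Gains were most frequent at sites of intermediate control level. Listed sites made up 18.1% of the 3001 sites with a control level from 40 to 60% and 17.8% of the 5344 sites from 20 to 40%, against 1.43% of the 7631 sites below 5%. None of the 1458 sites at 80% or more was listed, where a gain above 20 points has little or no room. Leaving out any 1 of the 4 libraries left no site past the limma threshold, with 4805 to 5363 sites at an unadjusted p under 0.05 and 1 residual degree of freedom; with both tables joined, 284 to 720 sites rose. With control levels of 5 to 95%, 2813 sites rose and 228 fell. In simulated data for this comparison, a rise of 20 points was recovered at 1.5% of sites, 30 points at 31.3% and 50 points at 98.5%.

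Livers that lost both genes in adulthood differed from controls at the listed sites by 1.86 points, less than the SD between controls. The mean was 30.0% ± 0.107 in adult nulls and 28.1% ± 2.30 in controls over 2267 listed sites in both tables, and 19.2% ± 0.327 against 20.9% ± 1.195 at 26387 other sites (exact permutation p = 0.333, n = 2 and 2, the smallest possible). These controls had also served, with the developmental nulls, to choose the list. By limma on the adult table, which sets 1 control against 2 adult nulls with 1 residual degree of freedom, no site rose and none fell, with 2067 of 28659 sites at an unadjusted p under 0.05. With both tables joined, 0 sites passed (1 higher and 3 lower with control levels of 5 to 95%) and 2299 had an unadjusted p under 0.05; in simulated data for that fit, a rise of 30 points was recovered at 79.1% of sites.

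The developmental and adult nulls were also compared directly. By limma on the joined tables, 2243 sites were higher and 59 lower in developmental nulls, and 1572 of the higher sites were listed. Listed sites had 59.8% ± 0.311 in developmental nulls and 30.0% ± 0.107 in adult nulls. The 26387 other sites had 22.6% ± 0.111 and 19.2% ± 0.327 (exact permutation p = 0.333 for each class, n = 2 and 2, the smallest possible). These developmental nulls had served to choose the list, so the listed share and the listed levels are no independent evidence here. Without adult null 1 or 2, 218 and 208 sites were higher and 7 and 11 lower, and without developmental null 1 or 2, 764 and 701 were higher and 25 and 18 lower.

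The age series asked whether the methylation difference holds from 20 days to 6 months. Tiles in listed sites had a mean level of 48.3% ± 4.398 (n = 4) in developmental nulls and 27.8% ± 9.44 (n = 4) in controls over 127 tiles, a difference of 20.5 points (exact permutation p = 0.029, the smallest possible). Paired by age the list difference was also 20.5 points, but 4 pairs cannot give an exact p under 0.05. At 4636 tiles of other FoxA sites the difference was 0.789 points (exact permutation p = 0.543, n = 4 and 4). Most of these tiles had levels far below those of the list. At the 452 with a mean level of 10 to 50%, nulls had 26.1% ± 7.58 and controls 21.1% ± 8.96 (exact permutation p = 0.429). Over 110 tiles measured in all 27 libraries, the list level in controls was 42.0% at 20 days, 26.6% at 8 weeks, 22.8% at 4 months and 20.0% at 6 months. In developmental nulls it was 54.3%, 50.9%, 43.5% and 46.8% at the same ages. Differences were 12.3, 24.3, 20.7 and 26.8 points, from 1 library per group and age, so that no single age was tested.

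**Figure D1:**
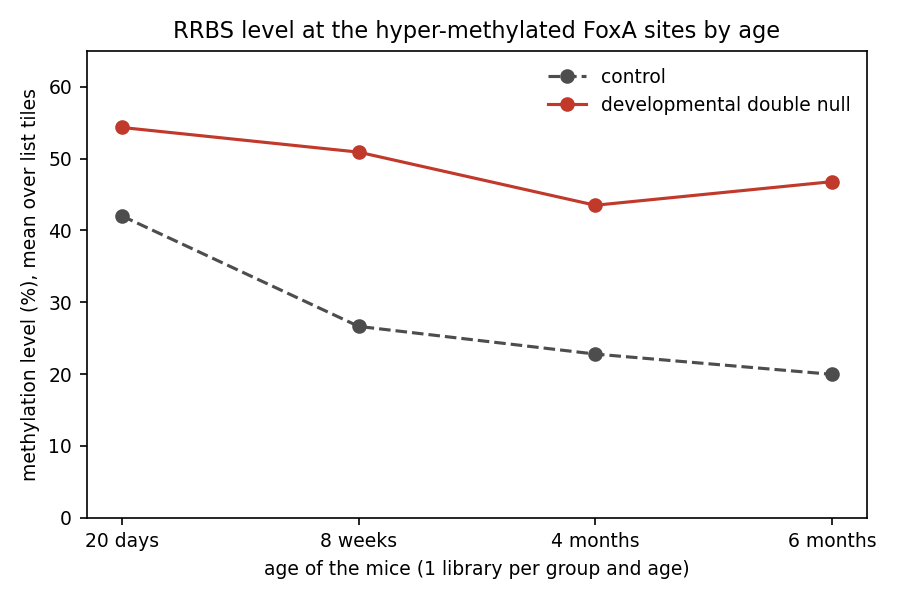
Mean RRBS methylation level (%) over 110 tiles inside listed FoxA sites, by age, with 1 control library and 1 developmental double null library at each age; the lines join the ages. The control level is 42.0% at 20 days and 20.0% at 6 months, and the null library lies above its control at each of the 4 ages.

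By limma, 650 of 369462 tiles rose and 231 fell in the age series, 24 of the rising tiles being in the list (81 higher and 1 lower when adjusted over the list alone). With a block by age, 2149 rose and 1018 fell. The falling tiles depended on the setting, as 343 rose and 31 fell by at least 20 points, and 514 rose and 89 fell with mean levels of 5 to 95%. The tile at chromosome 10, 19852901 to 19853000, outside the list, had 75.3% ± 5.58 in developmental nulls and 7.24% ± 3.99 in controls (SE 3.58, limma adjusted p = 3.71e-09). The listed tile at chromosome 16, 32462101 to 32462200, had 80.2% ± 15.1 against 14.9% ± 4.71 (adjusted p = 0.0017). At chromosome 4, 43428801 to 43428900, the level was 18.7% ± 16.4 against 86.9% ± 6.87 (adjusted p = 0.0012). Other splits of the 8 libraries, each with both 20-day libraries on 1 side, reached as many tiles, so chance could not be excluded over all splits. Without the 20-day control 1390 tiles rose and 597 fell, without the 4-month null 1162 rose, and without the 4-month control, the 6-month control or the 20-day null 442, 394 and 370 fell.

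Adult triple nulls were compared with controls that also lacked Foxa3, so the contrast is loss of Foxa1 and Foxa2 in livers without Foxa3. The list level differed from controls by -0.392 points at 7 days and -1.23 points at 13 days after Cre, within the spread between nulls. List tiles had 30.6% ± 1.13 (n = 3) in day 7 nulls and 31.0% ± 0.275 (n = 3) in their controls (exact permutation p = 0.7, smallest possible 0.1). At day 13 they had 27.9% ± 2.17 and 29.1% ± 0.383 (n = 2 and 2, exact permutation p = 1, smallest possible 0.333). Over the 110 tiles measured in all 27 libraries, the differences were 21.0 points in the age series, -1.04 at day 7 and -1.04 at day 13. There the list difference of the age series exceeded that of day 7 by 22.1 points (exact permutation of null and control labels, p = 0.0029). It exceeded that of day 13 by 22.1 points (exact permutation p = 0.0143). Both tests assume no effect in either experiment, so a large age series difference alone can give a small p. They do not test whether the differences are equal. Over each comparison's own tiles, the differences without null 2 were 0.177 points at day 7 and 0.303 at day 13. Relative to other FoxA sites the day 7 difference was 1.04 points, because those other sites themselves differed by -1.43 points (exact permutation p = 0.1, the smallest possible). At day 13 the other FoxA sites differed by -1.037 points (exact permutation p = 0.333, the smallest possible).

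By limma, 6 tiles rose and 14 fell at day 7, and 12 rose and 21 fell at day 13, with none in the list; 19703 and 20675 tiles had an unadjusted p under 0.05. In simulated data with the same spread in every group, a rise of 30 points was recovered at 20.9% of tiles for day 7 and 7.5% for day 13. For the age series it was recovered at 41.8%. At day 7, 12 of the 20 tiles lay on chromosome 5, which held 7.40% of the tested tiles (Fisher's exact test with neighbouring tiles counted separately, adjusted p = 3.64e-08 over the chromosomes). The tile at chromosome 5, 106349001 to 106349100, was at 0% in all 3 nulls and 78.6% ± 12.7 in controls (limma adjusted p = 4.99e-06), and that at 139180101 to 139180200 at 25.9% ± 0.73 against 73.4% ± 6.54. At day 13 the widest difference was at chromosome 1, 163069101 to 163069200, with 54.5% ± 6.43 against 100% in both controls. Day 7 counts were 3 rising and 13 falling with a difference of at least 20 points, 15 and 28 without control 2, 21 and 23 without control 3, and 3 rising without null 2. Day 13 counts were 54 and 50 on the logit scale, 6 and 8 with a difference of at least 20 points, 6 and 6 with levels of 5 to 95%, 37 and 92 without control 1, 446 and 172 without control 2, 101 and 269 without null 1, and 82 and 93 without null 2.

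**Figure D2:**
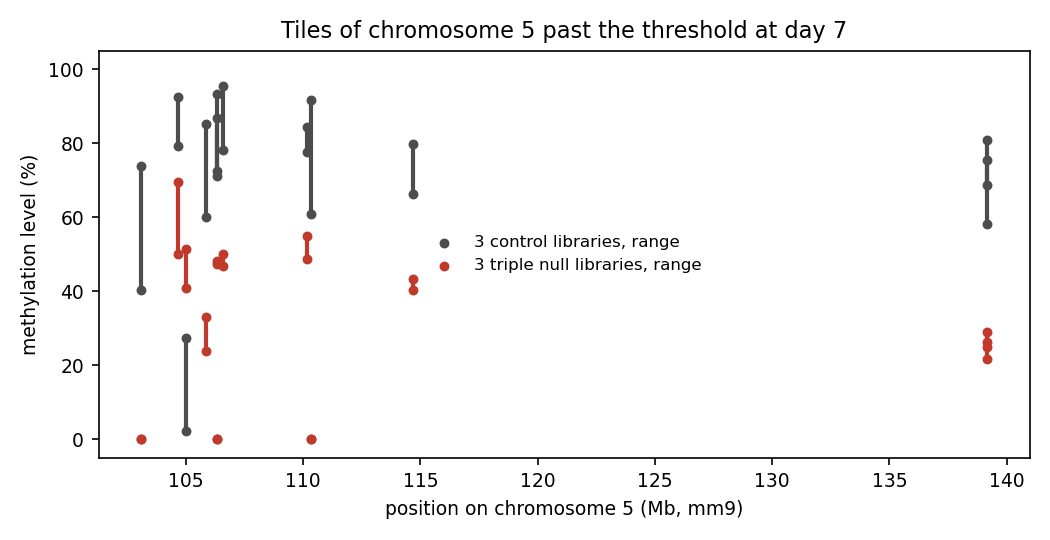
Methylation level (%) of the 12 tiles of chromosome 5 past the limma threshold at day 7, against position in Mb (mm9); each line spans the 3 control or the 3 triple null libraries and its dots are the lowest and highest. The null level lies below the control level at 11 of the 12 tiles, and is 0% in all 3 nulls at chromosome 5, 106349001.

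Adult double nulls after partial hepatectomy were compared with controls that also had partial hepatectomy. The contrast is loss of Foxa1 and Foxa2 in regrown livers, and the effect of regrowth itself was not tested. List tiles had 30.0% ± 1.21 (n = 3) in nulls and 26.7% ± 1.19 (n = 2) in controls, a difference of 3.31 points (exact permutation p = 0.2, the smallest possible), and other FoxA sites differed by 0.129 points. Over the 110 tiles measured in all 27 libraries the difference was 2.56 points. That of the age series exceeded it by 18.5 points (exact permutation p = 0.0714, assuming no effect in either experiment). By limma 5 tiles rose and 4 fell, none of them in the list, with 22529 at an unadjusted p under 0.05; in simulated data a rise of 30 points was recovered at 17.9% of tiles. At chromosome 17, 35070901 to 35071000, the level was 69.9% ± 8.96 against 7.64% ± 4.91 (adjusted p = 0.0014), and at chromosome 10, 121885101 to 121885200, 5.28% ± 2.68 against 23.9% ± 1.61 (adjusted p = 0.0299). On the logit scale 3 rose and 9 fell, 4 rose and 0 fell by at least 20 points, and 5 rose and 0 fell with levels of 5 to 95%. Without control 1 the counts were 211 and 107, without control 2 they were 209 and 186, and without null 1, 2 or 3 the falling tiles numbered 7, 9 and 9, with 9 rising without null 3.

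Livers that kept Foxa alleles lay 4.89 and 3.95 points above controls at listed sites. These mutants were 8 weeks old, while the 4 controls ran from 20 days to 6 months. Over 110 shared tiles the single 8-week control had 26.6%, against 33.1% with 1 Foxa2 allele left and 32.3% in double heterozygotes. With 1 Foxa2 allele left the list level was 33.5% ± 0.214 (n = 2) against 28.6% ± 9.49 in the 4 controls (exact permutation p = 0.533), and in double heterozygotes 31.1% ± 2.41 (n = 2) against 27.1% ± 9.84 (exact permutation p = 0.667). Developmental nulls were 15.8 points above the first genotype and 16.6 above the second over 110 shared tiles. They also lay above them by less elsewhere, by 2.38 and 2.82 points at other FoxA tiles and by 2.245 and 2.055 over all tiles. Each exact permutation test gave p = 0.133, the smallest possible (n = 4 and 2). These nulls were of the age series, from 20 days to 6 months old, so genotype, age and experiment were not separated.

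**Figure D3:**
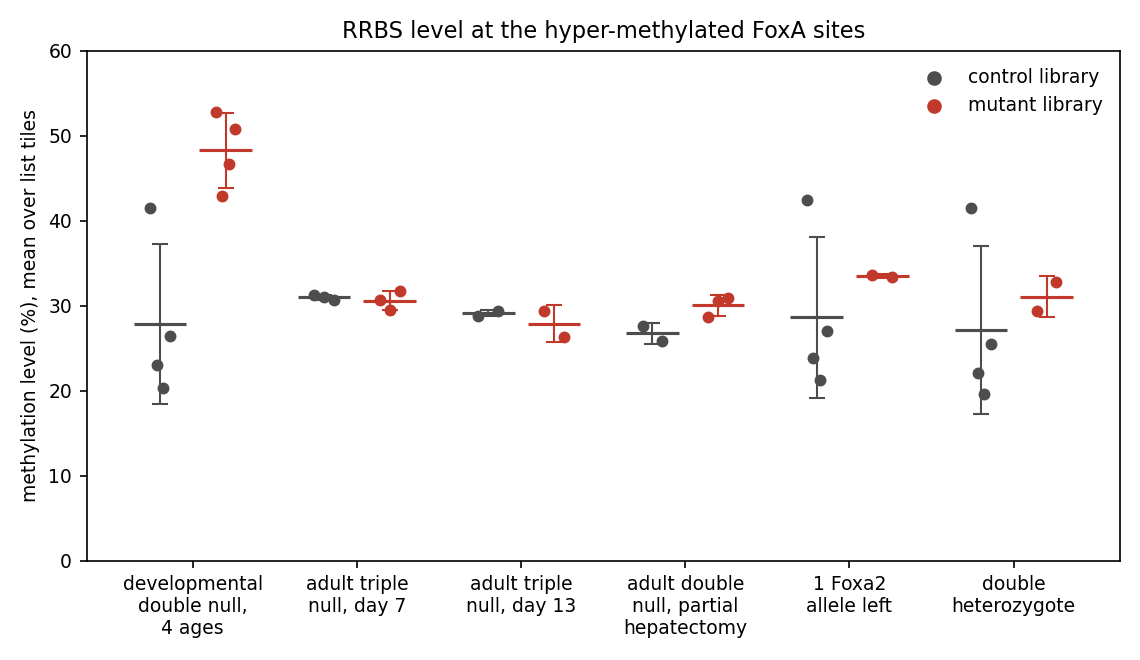
Mean RRBS methylation level (%) over tiles inside listed FoxA sites in each library (dots), with group mean (bar) and SD (whiskers), for 6 comparisons of mutants with their controls; the last 2 comparisons use the control libraries of the age series. Developmental nulls lie between 42.9 and 52.8%, and their controls between 20.3 and 41.5%.

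By limma 410 tiles rose and 22751 fell with 1 Foxa2 allele left, and 467 rose and 23328 fell in double heterozygotes. At chromosome 6, 48518601 to 48518700, the level was 62.1% ± 13.7 and 77.9% ± 8.69 in these genotypes against 5.87% ± 5.70 in the controls they share. Far from FoxA sites, tiles of mean level below 10% had 1.80% ± 0.184 and 1.69% ± 0.114 in these genotypes and 3.78% ± 0.264 in the age series controls, against 1.55 to 1.68% in the controls of the other experiments. All 8 libraries of the age series, null or control, lay at 3.45 to 4.13% at these tiles, the 8-week control at 4.13%, and the 4 mutants, 8 weeks old, at 1.61 to 1.93%. The mutants thus lay near the controls of other experiments, which argues against a genotype effect at these low distant tiles. By chromosome, the median absolute difference of tiles past the threshold was 2.93 to 3.16 points with 1 allele left. In double heterozygotes it was 2.92 to 3.21 points. For the remaining tiles genotype and experiment cannot be told apart in these counts. The counts with a difference of at least 20 points were 175 and 757 with 1 allele left, and 225 and 846 in double heterozygotes, and on the logit scale 1302 and 1543 rose. With levels from 5 to 95% the counts were 37 and 283, and 47 and 364; without mutant 1 or 2, 254 and 432 rose and 4365 and 3659 fell with 1 allele left, and 137 and 232 rose and 3042 and 2684 fell in double heterozygotes. Without the 20-day control 742 and 891 tiles rose. The list differences were 9.48 and 8.72 points without that control, and 2.42 and 1.43 without the 6-month control; that of double heterozygotes was 2.25 points without the 4-month control and 2.24 without mutant 2. With the spread taken from only the 2 groups compared, limma passed 0 tiles in each of the 6 RRBS comparisons, with 20060 to 50675 at an unadjusted p under 0.05.

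HNF6 lists of developmental nulls held fewer of the control regions than adult null lists. Developmental null lists came from MACS 2.1.1, with median peak widths of 87.5 and 82 bp, and adult null lists from MACS 1.4.3, with 307 and 320 bp. An overlap of 1 bp counts, which favours wide peaks, so genotype and caller cannot be told apart in this contrast. Of 1078 regions with a peak in all 3 control lists, 61.0% (Wilson 95% interval 58.1 to 63.9) and 45.2% (42.2 to 48.2) were found in the developmental null lists, and 89.5% (87.6 to 91.2) and 86.9% (84.8 to 88.8) in the adult null lists. Control lists 1, 2 and 3, left out in turn, held 92.2% of 1168, 88.2% of 1220 and 30.4% of 3541 regions shared by the other 2 controls. Peaks per library numbered 5767, 4652 and 1770 in controls, 3122 and 1188 in developmental nulls (exact permutation p = 0.4, n = 2 and 3) and 4028 and 5678 in adult nulls (p = 1, exact, smallest possible 0.2). Without control 3, the mean share found was 24.9% in developmental nulls and 78.0% in adult nulls, and the adult difference in peaks, 790.0 in all libraries, was -356.5; without adult null 2 it was -35.

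At listed sites, 0.240% ± 0.183 carried an HNF6 peak in developmental nulls and 2.50% ± 1.58 in controls (exact permutation p = 0.2, the smallest possible). In adult nulls 2.20% ± 0.758 did (exact permutation p = 0.8, n = 2 and 3). At other FoxA sites the shares were 1.41% ± 0.543 in developmental nulls, 5.81% ± 3.36 in controls and 7.82% ± 1.78 in adult nulls (exact permutation p = 0.2 and 0.6). The lower share in developmental nulls was thus not particular to listed sites. Of the 16 control regions at listed sites, 10 and 12 were found in adult nulls, against 368 and 374 of 382 at other FoxA sites (Fisher's exact test, p = 4.27e-05 and 7.18e-04, adjusted over 5 tests 1.07e-04 and 0.001). Of the 680 control regions at no FoxA site, 587 and 551 were found in adult nulls, a share also below that at other FoxA sites. In developmental nulls 6 and 3 of the 16 were found, against 206 and 151 of the 382, which did not pass (Fisher's exact test, p = 0.212 and 0.119, adjusted 0.212 and 0.148). Listed sites less often had a control region at all, 0.78% of them against 2.14% of 30597 other sites (Fisher's exact p = 1.04e-07, adjusted 5.18e-07). Overlapping sites were counted separately in this test, so its p can be too small. Sites were also not matched on control methylation. In WGBS controls 1 and 2, sites with a control region had 9.13% and 11.59%, against 20.79% and 22.59% at sites without. Listed sites had a control mean of 28.2%, so the lower share cannot be told apart from a difference in control level. Adult lists came from another version of the peak caller, with wider peaks.

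**Figure D4:**
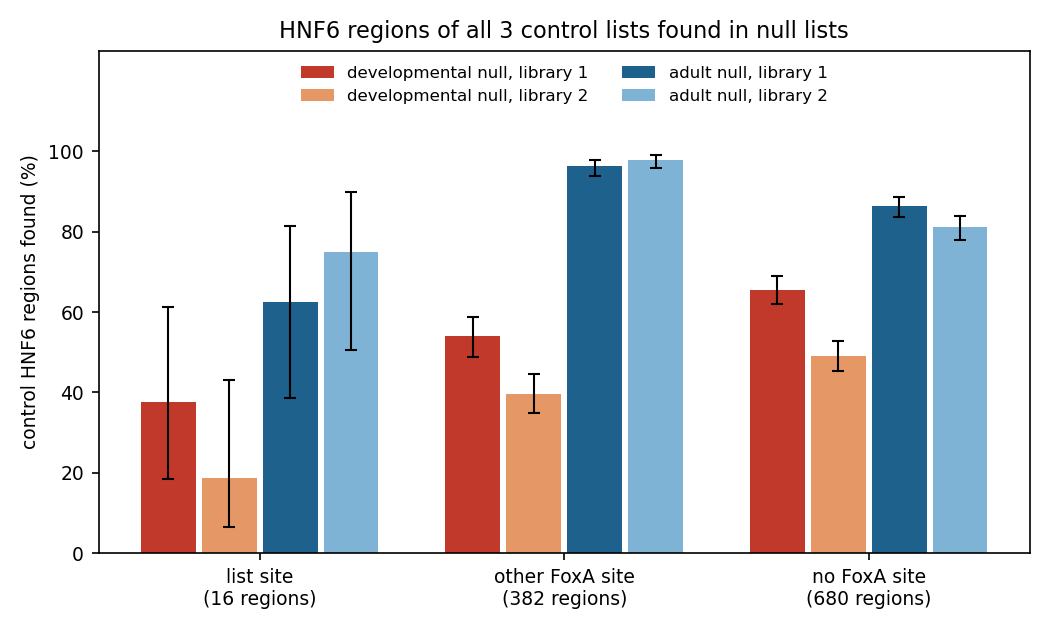
Share (%) of HNF6 regions of all 3 control lists that were found in each null list, for 16 regions at listed FoxA sites, 382 at other FoxA sites and 680 elsewhere; whiskers are Wilson 95% intervals. In adult nulls the share is 62.5 and 75.0% at listed sites, 96.3 and 97.9% at other FoxA sites and 86.3 and 81.0% elsewhere.

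Among 25 peaks in all controls and no null, the best scored lay at chromosome 6, 42204512 to 42204723 (authors' fold enrichment 21.1), and the second at chromosome 19, 26494409 to 26494621, in a listed site (authors' fold 20.0). Listed sites held 4 of the 10 best scored. Peaks of both developmental nulls and no control numbered 67, of which the 5 best scored lay on chromosomes X and Y, 3 of them within 1000 bp of a peak in 1 or more control lists. Peaks of both adult nulls and no control numbered 273, the best scored at chromosome 19, 53478693 to 53479088 (authors' fold 32.0).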

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

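The direct tests between developmental and adult loss, the test of a shift of all tiles, and the counts of splits were chosen only after the results were seen.

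Over the 110 list tiles measured in all 27 libraries, the difference of the age series exceeded that of day 7 triple nulls by 22.0563 points (exact permutation p = 0.0029) and that of day 13 by 22.0615 points (exact permutation p = 0.0143). Its excess over hepatectomy double nulls, 18.5 points, did not pass (exact permutation p = 0.0714). Each of these tests assumes no effect in either experiment, so a large age series difference alone can give a small p. They do not test whether the differences are equal. In WGBS, 2243 sites were higher and 59 lower in developmental than in adult nulls by limma. In none of the 8 sets of values over 4 libraries that were tested did a library lie past Dixon's limit.

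The higher level at list tiles in developmental nulls of the age series was weighed against a technical explanation. A shift of all tiles was argued against, since the difference relative to all tiles was 19.8 points (exact permutation p = 0.029). Loss of FoxA in development may underlie the difference, as a hypothesis. A different share of other cell types and the depth of the libraries were not tested and stay open.

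Over all splits, chance could not be excluded for the count of age series tiles. Of the 35 splits of the 8 libraries, 4 gave as many tiles as the real 881, the highest other giving 1368. That split set the 4- and 6-month libraries of both genotypes against the 20-day and 8-week libraries, so it followed age. The other 2, with 946 and 918 tiles, also had both 20-day libraries on 1 side, so that all 3 mix age into the count. The 7 other splits with each age on both sides gave 134 to 221 tiles; 8 such splits, the real one included, are too few for a share under 0.05. For day 7, 1 of 10 splits, the real one, gave 20 tiles and the highest other 3; 10 splits are too few for a share under 0.05.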

How the results depend on the processing

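The joined WGBS tables, the best 1000 peaks and relative levels were alternatives chosen after seeing the data. Of 83 alternatives for mean levels 71 were labelled unchanged, as were 35 of 46 for HNF6. Of 178 counts 82 stayed within 1.5 times. Outside the age series list level, neither mean levels nor HNF6 tests could pass the threshold, as their smallest possible p was 0.1 or more. There only direction could change, and 3 mean levels and 5 HNF6 values reversed. The 9 mean levels labelled weaker were of the age series, where the exact p was 0.057 or 0.125, the smallest possible. HNF6 shares of control regions found have no p-value and were judged by the size of the change. Where a value moved the cause was not tested, except that fewer libraries or tiles enter by construction. The coverage minimums were not run, since the tables give no coverage, and the adult WGBS table, with 1 control, allowed no library to be left out; a leave-out of it was run on the joined tables, with 0 sites each time. Unknown depth limits every level.

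In WGBS, control levels of 5 to 95% gave 2813 sites higher and 228 lower for the developmental null, and 1 and 3 for the joined adult fit; joining the tables gave 181 lower. Each library left out gave 0 to 720 higher and 0 to 67 lower, the higher ends from the joined tables.

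The age libraries were not treated as paired, as not every pair of the same age correlated above 0.1: r was 0.366 at 20 days, 0.109 at 4 months, 0.149 at 6 months and 0.06 at 8 weeks, and the 4-month null correlated better with the 6-month control, at 0.13. With a replicate block, 42 WGBS sites were lower, the age series gave 2149 and 1018 tiles and a list difference of 20.5 points with exact p = 0.125, the smallest possible, and hepatectomy gave 8 and 7. No other count moved by over 1.5 times with the block.

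With only the 2 groups compared, all 6 RRBS comparisons gave 0 tiles higher and 0 lower. A difference of at least 20 points gave 343 higher and 31 lower in the age series, 3 higher at day 7, 6 and 8 at day 13, 0 lower for hepatectomy, 175 and 757 with 1 Foxa2 allele left and 225 and 846 in double heterozygotes. Levels of 5 to 95% gave 89 lower in the age series, 6 and 6 at day 13, 0 lower for hepatectomy, 37 and 283 with 1 allele and 47 and 364 in double heterozygotes. The logit scale gave 54 and 50 at day 13, 3 and 9 for hepatectomy, 1302 higher with 1 allele and 1543 higher in double heterozygotes.

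Leaving out each library gave, for tiles higher and lower, 514 to 1390 and 275 to 597 in the age series, 3 to 21 and 10 to 28 at day 7, 37 to 446 and 92 to 269 at day 13, 7 to 211 and 7 to 186 for hepatectomy, 254 to 742 and 3659 to 24208 with 1 allele, and 137 to 891 and 2684 to 24978 in double heterozygotes. List differences ranged from 18.0 to 25.0 points in the age series, each with exact p = 0.057, the smallest 7 libraries allow, from -0.951 to 0.177 at day 7 (above 0 without null 2) and from -2.76 to 0.303 at day 13 (above 0 without null 2). They ranged from 2.42 to 9.48 points with 1 allele and from 1.43 to 8.72 in double heterozygotes. Relative to other FoxA sites the day 7 difference was 1.04 points, and that of double heterozygotes was 5.99. The other FoxA sites themselves differed by -1.43 points at day 7 and by -2.04 in double heterozygotes.

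For HNF6, better-scored peaks gave shares found of 40.7% and 93.2%. Leaving out each library gave 24.9 to 61.0% for developmental and 78.0 to 89.5% for adult nulls, -356.5 to 1642 for the adult difference in peaks (lowest without control 3, and -35 without adult null 2), and -1.18 to 0.333 points for the adult difference in listed sites with a peak, which was 0.0863 with the best 1000 peaks.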

Other observations

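The clustering draws, the choice of sites on single library pairs, the peak caller test and the chromosome 5 tests were chosen only after the result was seen; the test of score-matched HNF6 regions was written before its result.

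Listed sites lay near each other along the chromosomes. In a one-sided permutation test with overlapping sites joined, 292 of 2323 listed regions (12.6%) had another listed region within 10000 bp, against a mean of 208 in 1000 draws of as many FoxA regions per chromosome (highest 273) and 193 in draws also matched on control level (highest 263); p = 0.001 each, the smallest the draws can give. With overlapping sites counted separately, 366 sites had such a neighbour, and 3 of 1000 draws by chromosome were as high (permutation p = 0.004). The longest run held 5 separate listed sites at chromosome 2, 67809186 to 67824279, with 15.6% ± 1.4 (n = 2) in controls and 55.3% ± 3.92 (n = 2) in developmental nulls. A run of 3 at chromosome 4, 82860698 to 82871906, had 16.9% ± 1.37, 58.3% ± 7.59 and, in adult nulls, 17.0% ± 0.22. Sites chosen by a gain above 20 points between 1 developmental null and 1 control of WGBS differed by 23.5 and 28.0 points between the other null and the other control, where adult nulls differed from that control by -1.37 and 1.78 points. By chromosome, no share of listed sites passed the test (lowest adjusted Fisher p = 0.0888, chromosome 1).

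FoxA tiles of low level outside the list had 1.28% ± 0.268 (n = 3) in day 7 triple nulls and 2.44% ± 0.054 (n = 3) in controls over 3650 tiles (exact permutation p = 0.1, the smallest possible), and 1.47% ± 0.190 against 2.24% ± 0.477 at day 13. Low tiles far from FoxA sites differed by -0.147 and -0.18 points in the same comparisons, and low FoxA tiles of hepatectomy nulls by -0.053. The lower level in triple nulls was not limited to low tiles. Over all 5451 FoxA tiles outside the list, day 7 nulls had 7.66% ± 0.378 and controls 9.09% ± 0.054 (exact permutation p = 0.1). FoxA tiles outside the list of mean level 10 to 50% differed by -2.615 points at day 7 and -1.998 at day 13. Distant tiles of that level differed by -0.618 and -1.043. Of a library's own HNF6 peaks, 14.2% ± 3.88 lay at a FoxA site in developmental nulls, 28.6% ± 5.16 in controls and 32.8% ± 0.446 in adult nulls (exact permutation p = 0.2 for each null, n = 2 and 3, the smallest possible).

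Adult nulls held fewer of the control HNF6 regions at listed sites, 62.5% and 75.0% of 16, than at other FoxA sites. At the 680 regions with no FoxA site they held 86.3% and 81.0%, also below other FoxA sites. Weaker control peaks there were argued against, since regions at other FoxA sites matched on control score were found at 93.75% and 95.0%, above the upper bounds of 81.5% and 89.8% at listed sites. The 96.3% and 97.9% found over all regions at other FoxA sites are part of the contrast itself and decide nothing on the other caller version, which stays open. Adult loss of FoxA may lower HNF6 binding more at listed than at other FoxA sites, a hypothesis that rests on 16 regions. Against regions with no FoxA site the listed share was not clearly lower, as its interval in adult null 2, 50.5 to 89.8%, held 81.0%. Peak width and the share of each cell type stay open.

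Day 7 calls on chromosome 5 lay close together. The 10 separate tiles were on average 9.66 Mb apart, against 47.1 Mb in 1000 draws of tiles of the chromosome (lowest 12.1 Mb, one-sided permutation p = 0.001, the smallest the draws can give). A shift of all tiles was argued against, since all tiles differed by 0.227 points (exact permutation p = 0.6, n = 3 and 3) while the 11 lower tiles of chromosome 5 fell by 28.2 to 78.6 points. Sequence variants of a linked segment that differ between the mice may underlie these calls, with levels of 0% in all 3 nulls at 3 tiles; the spacing was tested because it had been seen. No biological explanation was tested, and no genotype of the segment was used here.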
